A study of Homo sapiens with 12 samples.

How the data were processed

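Polyadenylated RNA from H9, an established human embryonic stem cell line, was measured by RNA sequencing in 12 libraries that fall into 4 groups of 3 replicates. The groups were undifferentiated cells (UNDIF), cells taken through neural differentiation (NEUR), and the same differentiation with the solvent DMSO (DMSO_NEUR, the vehicle) or with FT671 (FT671_NEUR), an inhibitor of the deubiquitinating enzyme USP7. The treatment field of the vehicle samples reads undifferentiated while their titles and descriptions read neural, and the titles were followed. Dose and duration of FT671 were not given in the labels. The labels do not say whether replicates were separate cultures, so p-values measure the spread between these libraries only. Replicate numbers did not pair libraries across groups, and no block was used.

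Per the submitters' processing notes, reads were processed with STAR, HTSeq and DESeq2 under R 4.3.1 on the hg19 genome, and parameters, annotation and the choice of genes were not stated there. The deposited signal is a normalized expression value made by the authors: gene read counts divided by 1 size factor per library, plus 1. The deposited p-value column is the authors' FDR for undifferentiated against neural cells, and the test behind it was not stated. The smallest deposited value was 1. After subtraction of 1, each library's values were whole multiples of 1 step, and 100% of values gave whole reads within a tolerance of 0.001 (largest deviation 4.35e-05). Recovered totals ran from 15906471 to 17271155 reads per library over the 13310 genes of the table, which are not the full sequencing depth. Relative size factors ran from 0.942 to 1.08. The analysis plan had assumed read counts with an alternative for normalized values, and that alternative was used. The title of the deposited sheet names a USP7 heterozygote, while the labels give a wild-type genotype for all 12 samples. The labels were followed, and the genotype was not checked from the values. A further 32 of the 47 columns, which hold other samples or annotation, were not used.

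The unit of values below is the normalized read count, the deposited value minus 1. Each gene was tested with limma 3.58.1 (R 4.3.3) on log2 of the normalized count plus a pseudocount of 1, in 1 linear model with a mean for each of the 4 groups over all 12 libraries, with empirical Bayes variances and a trend on expression. Adjusted p-values are Benjamini-Hochberg values over 13310 genes for each of 5 comparisons, and a gene was called at an adjusted p under 0.05 with no fold minimum. All 13310 genes had more than 1 CPM (reads scaled to a common library total) in at least 3 libraries, and the smallest mean was 12.2 normalized counts, so no further filter was applied. Genes are identified by Ensembl gene identifier and symbol. The table gave no symbol for 763 genes, of which 534 were named from the identifier. Chromosome positions are not given, because the annotation at hand was for another genome build than the authors' alignment. The strand and the reads shared between paralogs could not be checked from gene totals.

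Before the data were examined, 23 gene lists were fixed: pluripotency, neural progenitor, neurogenesis and early neuron, neural crest, mesoderm, endoderm, surface ectoderm with amnion and trophoblast, mesenchyme and matrix, glia, p53 targets, PRC1.1 subunits, other Polycomb subunits, HOX, cell cycle, integrated stress and unfolded protein response, TGF-beta and BMP targets, WNT targets, Notch targets and ligands, midbrain with hindbrain and spinal cord, ventral and hedgehog, cholesterol synthesis, hypoxia and glycolysis, and germline. Lists with at least 3 tested members were tested by limma camera with a preset inter-gene correlation of 0.01, on log2 CPM (prior count 2) from recovered reads, with Benjamini-Hochberg adjustment over lists within a comparison. The HOX list had too few tested members, and its counts are not reported here. Camera with a correlation estimated per list and fry were alternatives. A further 8 lists were written after these results were seen: epithelial junctions, squamous epithelium, trophoblast, antigen presentation by class I, interferon response, imprinted genes, ribosomal proteins and lysosome. Each library was left out in turn for these lists as well. Their results stand among the other observations.

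The rule for named genes was fixed before the data were examined as well. For neural against undifferentiated and for FT671 against vehicle it takes USP7 and the PRC1.1 subunits, the 8 largest rises and 8 largest falls among called genes with a symbol, a mean log2 CPM of at least 1 and groups that do not overlap, and up to 4 called members per list with the largest fold change. For vehicle against untreated it takes up to 4 rises and 4 falls and the list members. Other genes are described as chosen after their values were seen.

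The fold of a gene with no reads in 1 group is a lower bound against a floor of 3 reads over the 3 libraries of that group. Ratios against 1 to 3 reads carry a 95% counting interval from the exact binomial distribution of the reads. Intervals and floors cover counting error only, since reads carry no molecular identifiers. A differentiation score per library was the mean log2 CPM of the 200 genes with the largest rise minus that of the 200 with the largest fall in neural against undifferentiated cells. It was compared between vehicle and FT671 by an exact two-sided permutation test. The libraries of these 2 groups did not enter the fold changes that ranked the genes. They did enter the limma variance behind the calls and the mean log2 CPM of at least 1 that the genes had to pass.

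The procedure was tested on simulated data with 100 genes changed 2-fold and 100 changed 4-fold among 13310. In that test limma called 99 and 100 of them, with 14 false calls among 13110 unchanged genes. DESeq2 1.42.0 called 97 and 99 with 23 false calls, and edgeR 4.0.16 called 97 and 99 with 13. The simulated changes were equally up and down, left out genes low in vehicle and kept the real size factors. In the real data 79.8% of genes were called between FT671 and vehicle. The simulation therefore does not cover the scaling or the error rate where most genes change. Alternatives fixed in advance were median-of-ratios factors recomputed from the table, scaling by library totals alone, the DESeq2 Wald test, log2 CPM in limma, a fit of the 2 compared groups alone, replicate number as a block, an adjusted p under 0.01, pseudocounts of 0.1 and 10, filters on low values, each library left out in turn, and other gene numbers for the score. Alternatives added after seeing the data were the edgeR quasi-likelihood test, TMM scaling, a mean of at least 100 and a pseudocount of 2. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6.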

Results

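The 12 libraries compared H9 cells before and after neural differentiation, in which inhibitors of both SMAD branches are followed by a neural stem cell medium with EGF and bFGF, and differentiation in the presence of FT671 or its solvent. USP7, the target of FT671, removes ubiquitin from proteins including the p53 regulator MDM2 and is a partner of PRC1.1, a Polycomb complex built on BCOR and PCGF1. Undifferentiated libraries held 15906471 to 16072737 reads in the genes of the table, neural libraries 16404262 to 17104970, vehicle libraries 17149947 to 17198800 and FT671 libraries 17107952 to 17271155. Values are mean normalized read counts ± SD of 3 libraries, and folds are from limma with their standard error unless stated.

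Across the 13310 genes, log2 values correlated between replicates with Pearson r of 0.988 to 0.995, where genes are not independent replicates. Neural and vehicle libraries correlated at 0.987 to 0.994. Vehicle and FT671 libraries correlated at 0.807 to 0.818, and undifferentiated and FT671 libraries at 0.656 to 0.664. FN1, which encodes the matrix protein fibronectin, took 3.71% ± 0.0898 (SD, n = 3) of reads with FT671 and 0.134% ± 0.00492 with vehicle. NEUR replicate 3 stood apart from the other untreated neural libraries, and its deviation correlated across genes with transcript length (Spearman rho −0.643).

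The comparison of untreated neural with undifferentiated cells asks what neural differentiation changed. Genes of the pluripotent state fell, some of them to a few reads. POU5F1 (ENSG00000204531), a core transcription factor of pluripotency, had 2459 ± 172 counts in undifferentiated and 0.978 ± 0.978 in neural cells, a ratio of 2498 with a counting interval of 854 to 12115. The NODAL co-receptor gene TDGF1 was at least 691-fold lower, from 680.5 ± 52.7 counts to 0, and VRTN fell from 2459 ± 152 to 4.28 ± 2.33. Of the 18 pluripotency genes tested, 17 fell and 0 rose, and the same numbers passed when adjusted over the list alone. The list was lower by limma camera (adjusted p = 1.65e-08, and adjusted p = 0.00607 with an estimated correlation).

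Neural progenitor genes changed in both directions. NR2F1, a transcription factor of the developing forebrain, rose from 6.30 ± 1.52 to 682.8 ± 36.1 counts (log2 fold change 6.57 ± 0.25, adjusted p = 3.45e-13). PAX6 (ENSG00000007372), a transcription factor of neural progenitors named here after its values were seen, rose from 176.4 ± 20.8 to 3519 ± 180 (4.32 ± 0.16, adjusted p = 1.63e-13). LHX5 fell from 1597 ± 160 to 14.7 ± 3.43 and ZIC2 from 2714 ± 154 to 86.0 ± 5.79, both of them transcription factors of early neuroectoderm. In the neural progenitor list 11 of 22 genes rose and 11 fell (camera adjusted p = 0.875), and its median, mean and test differed in sign. Among genes of neurogenesis and early neurons 10 of 19 rose and 7 fell (adjusted p = 0.856). EBF2 rose from 1.57 ± 1.09 to 73.5 ± 3.56 counts and the synaptic gene SNAP25 from 10.0 ± 1.92 to 99.7 ± 11.3, while DCX, a marker of migrating neurons, fell from 344.7 ± 21.7 to 39.3 ± 16.1.

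Targets of p53 rose together. PLK2, a stress-induced kinase, went from 327.8 ± 32.2 to 8460 ± 365 counts (log2 fold change 4.69 ± 0.08, adjusted p = 1.96e-17), and CDKN1A, which encodes the cell cycle inhibitor p21, from 613.3 ± 24.5 to 6623 ± 398 (3.43 ± 0.07, adjusted p = 1.50e-16). In this list 26 of 27 genes rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 2.83e-07, and adjusted p = 0.00607 with an estimated correlation). Genes of mesenchyme and matrix also rose, with 12 of 14 higher and 1 lower, or 13 and 1 adjusted over the list alone. Their camera adjusted p was 1.08e-04, and adjusted p = 0.150 with an estimated correlation. COL3A1, a fibrillar collagen gene, rose from 2.83 ± 2.49 to 262.6 ± 23.9 counts, the intermediate filament gene VIM from 3019 ± 173 to 47334 ± 5676, and ACTA2, which encodes smooth muscle actin, from 92.2 ± 13.5 to 1350 ± 112.

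Among the genes with the largest rises in neural cells were ITGB6, an integrin subunit (3.77 ± 2.48 to 1571 ± 228 counts), the cytokine gene TNFSF15 (16.4 ± 6.53 to 4517 ± 372) and GASK1B (0.310 ± 0.537 to 1657 ± 169, a ratio of 5278 with a counting interval of 947 to 208515). The largest falls included CRABP1, which binds retinoic acid (3054 ± 323 to 15.8 ± 5.32), LRAT, which esterifies retinol (1317 ± 33.5 to 9.84 ± 0.981), and APELA, a peptide hormone gene of pluripotent cells (2421 ± 408 to 20.7 ± 6.10). BCOR had 882.0 ± 46.2 counts in undifferentiated and 906.0 ± 106 in neural cells (adjusted p = 0.761), and USP7 had 3806 ± 113 and 3741 ± 165 (adjusted p = 0.698). YAF2, another PRC1.1 subunit, rose from 97.3 ± 8.69 to 262.5 ± 18.5.

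No other list passed the camera test in this comparison. Among cell cycle genes 5 rose and 17 fell of 29 (adjusted p = 0.227), and among WNT targets 2 rose and 7 fell of 10 (adjusted p = 0.305). SP5, a direct WNT target, fell from 693.9 ± 98.4 to 1.65 ± 1.52 counts. All 3 germline genes tested fell (adjusted p = 0.0992), DAZL from 942.9 ± 102 to 0.658 ± 0.570. Rises and falls were 9 and 7 of 16 for surface ectoderm with amnion and trophoblast (adjusted p = 0.807), 4 and 7 of 12 for neural crest (adjusted p = 0.794), 3 and 4 of 8 for mesoderm (adjusted p = 0.834), 1 and 2 of 4 for endoderm (adjusted p = 0.875) and 2 and 4 of 6 for glia (adjusted p = 0.807). They were 2 and 3 of 9 for PRC1.1 subunits (adjusted p = 0.973), 12 and 9 of 25 for other Polycomb subunits (adjusted p = 0.853), 9 and 6 of 19 for integrated stress (adjusted p = 0.807), 5 and 5 of 12 for TGF-beta and BMP targets (adjusted p = 0.856), and 3 and 4 of 10 for Notch (adjusted p = 0.933). They were 2 and 4 of 6 for midbrain, hindbrain and spinal cord (adjusted p = 0.807), 1 and 1 of 4 for ventral and hedgehog genes (adjusted p = 0.933), 6 and 8 of 16 for cholesterol synthesis (adjusted p = 0.807), and 9 and 4 of 16 for hypoxia and glycolysis (adjusted p = 0.807). By library totals alone they were 8 and 7 for hypoxia and glycolysis, 9 and 9 for integrated stress and 5 and 6 for TGF-beta and BMP targets. HOXB2, from the HOX list, which had too few members for a list test, was at least 99.2-fold higher, from 0 to 93.7 ± 28.5 counts. In each of these lists the counts were the same adjusted over the list alone.

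In all, limma called 10917 of 13310 genes between neural and undifferentiated cells, 5376 higher and 5541 lower, of which 2056 and 2200 changed at least 2-fold. Scaled by library totals alone, 4455 were higher and 6281 lower, and among genes with a mean of at least 100 counts more were higher (4833) than lower (4198). Without NEUR replicate 3, whose deviation followed transcript length, 10827 genes were called. The authors' FDR was under 0.05 for 10910 genes, of which 10819 were called here.

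**Figure D1:**
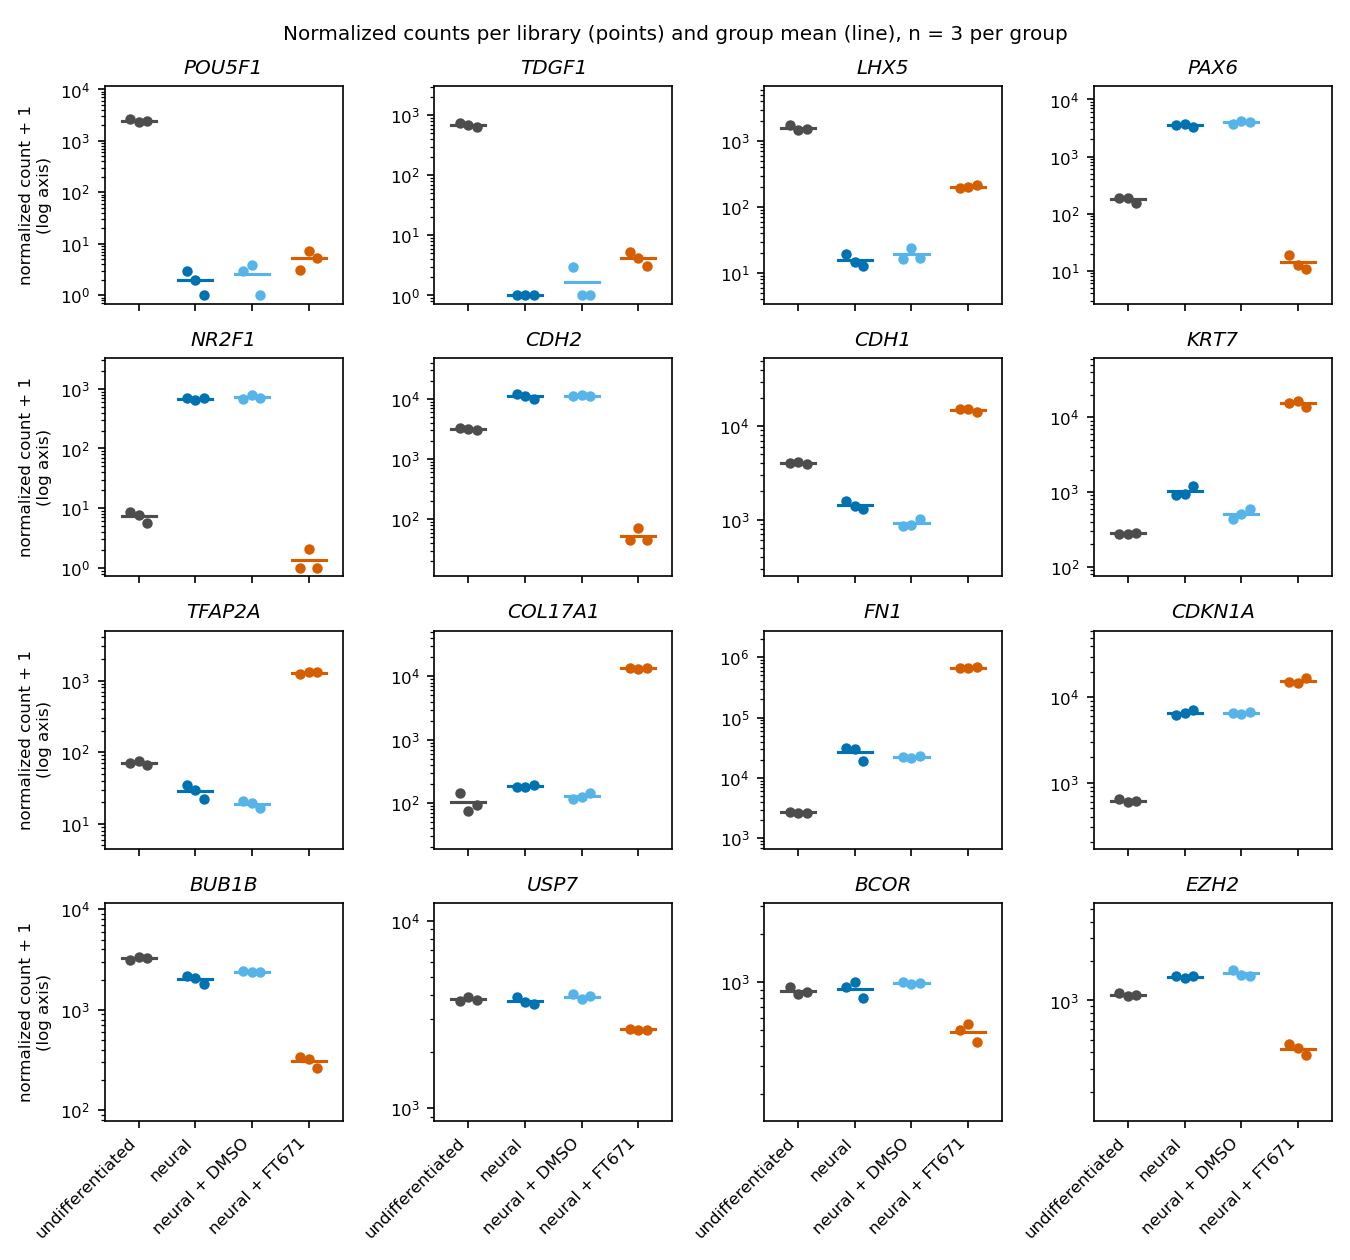
Normalized read counts (plus 1, log axis) of 16 genes in each of the 12 libraries, with 1 point per library, a line at the group mean and the 4 groups along each horizontal axis. PAX6 was near 3985 counts in vehicle and 13.0 in FT671 libraries, while COL17A1 was near 128.1 and 13386.

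The comparison of FT671 with vehicle asks what inhibition of USP7 changed during differentiation. Most neural progenitor genes fell with the inhibitor. PAX6 (ENSG00000007372) fell from 3985 ± 250 counts with vehicle to 13.0 ± 4.42 with FT671 (log2 fold change −8.19 ± 0.16, adjusted p = 1.03e-16). CDH2, which encodes the N-cadherin of neural epithelium, fell from 11311 ± 143 to 52.5 ± 14.7 (−7.76 ± 0.13, adjusted p = 2.03e-17), and the progenitor factor SOX3 from 812.4 ± 96.9 to 1.05 ± 1.05, a ratio of 768 with a counting interval of 263 to 3727. NR2F1 had 715.2 ± 52.0 counts with vehicle and 1 read over the FT671 libraries, a ratio of 2028 with a counting interval of 364 to 80155. Of 22 neural progenitor genes 17 fell and 1 rose, with the same counts adjusted over the list alone. The camera adjusted p was 1.80e-05, and adjusted p = 0.371 with an estimated correlation.

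Genes of neurogenesis moved in both directions, with 11 of 19 lower and 7 higher (camera adjusted p = 0.294). NCAM1, a neural adhesion molecule, fell from 2130 ± 178 to 21.9 ± 2.26 counts, the neuronal microtubule regulator STMN2 from 233.1 ± 6.92 to 4.94 ± 2.21 and TAGLN3 from 140.1 ± 6.42 to 3.52 ± 2.20. The largest falls over all genes included SFRP2, a secreted WNT modulator (50676 ± 3025 to 49.0 ± 21.6 counts, log2 fold change −10.07 ± 0.18, adjusted p = 6.38e-17). POU3F2, a neural transcription factor, was at least 409-fold lower, from 432.3 ± 29.7 counts to 0. ALDH1A1, an enzyme of retinoic acid synthesis, was at least 313-fold lower, from 331.1 ± 77.6 counts to 0.

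Epithelial genes of surface ectoderm, amnion and trophoblast rose with FT671. TFAP2A (ENSG00000137203), a transcription factor of surface ectoderm, rose from 17.8 ± 1.97 to 1282 ± 58.3 counts (log2 fold change 6.10 ± 0.17, adjusted p = 6.92e-15). GRHL2, a regulator of epithelial junctions, rose from 54.2 ± 12.8 to 1968 ± 211 (5.18 ± 0.15, adjusted p = 1.26e-14), and the keratin gene KRT7 from 508.9 ± 71.1 to 15355 ± 1420.1 (4.92 ± 0.11, adjusted p = 4.28e-16). In this list 15 of 16 genes rose and 0 fell, with the same counts adjusted over the list alone (camera adjusted p = 1.90e-07, and adjusted p = 0.194 with an estimated correlation). The list was already lower in vehicle than in untreated neural cells, where KRT7 had 1023 ± 151 counts. The largest rises over all genes included COL17A1, a component of epithelial hemidesmosomes (128.1 ± 14.9 to 13386 ± 193, 6.70 ± 0.16, adjusted p = 1.43e-15), SCEL, which encodes the cornified envelope protein sciellin (13.9 ± 3.96 to 1554 ± 34.1), the fatty acid transporter gene SLC27A6 (6.16 ± 3.68 to 1548 ± 15.4) and VGLL1 (13.0 ± 6.27 to 1367 ± 73.5).

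Cell cycle genes fell together. BUB1B, of the spindle checkpoint, fell from 2399 ± 42.4 to 309.5 ± 39.6 counts (log2 fold change −2.96 ± 0.09, adjusted p = 1.74e-14), and MCM2, a subunit of the replicative helicase, from 3619 ± 171 to 515.4 ± 67.5 (−2.82 ± 0.08, adjusted p = 1.03e-14). In this list 28 of 29 genes fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 3.59e-11, and adjusted p = 0.483 with an estimated correlation).

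Transcripts of USP7 and its partners changed in both directions. USP7 (ENSG00000187555) fell from 3940 ± 117 to 2630 ± 22.3 counts (log2 fold change −0.58 ± 0.06, adjusted p = 9.51e-08), and BCOR (ENSG00000183337) from 988.0 ± 13.1 to 487.5 ± 62.5 (−1.03 ± 0.10, adjusted p = 5.41e-08). RYBP fell by 0.51 and RNF2 decreased by 0.50 on the log2 scale, and PCGF1 rose from 124.5 ± 3.67 to 216.6 ± 30.4 counts. Of 9 PRC1.1 genes 5 fell and 2 rose (camera adjusted p = 0.503). Over all genes 79.8% were called in this comparison, 5347 higher and 5280 lower, so these counts do not set the complex apart. Among other Polycomb subunits 15 of 25 fell and 8 rose (adjusted p = 0.186), with the histone methyltransferase gene EZH2 down from 1613 ± 99.0 to 424.5 ± 38.9 counts.

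Of 27 p53 targets 16 rose and 4 fell (camera adjusted p = 0.186), or 15 and 7 with TMM scaling and 13 and 7 with library totals. CDKN1A rose from 6552 ± 215 to 15593 ± 1189 counts (log2 fold change 1.25 ± 0.07, adjusted p = 4.00e-11) and the stress cytokine gene GDF15 from 619.3 ± 26.6 to 2783 ± 753. Pluripotency genes split, with 7 higher and 6 lower of 18 (adjusted p = 0.824), or 6 and 7 with library totals as the scale. CDH1, the epithelial E-cadherin gene, rose from 918.1 ± 90.1 to 14810.1 ± 704 counts and L1TD1 from 74.2 ± 16.4 to 2498 ± 405, while LIN28A fell from 8861 ± 626 to 1097 ± 152. POU5F1, named here after its values were seen, had 4.23 ± 2.10 counts with FT671 and 1.62 ± 1.48 with vehicle. Matrix genes also split (6 higher, 8 lower of 14, adjusted p = 0.735), with FN1 up from 22445 ± 946 to 674350.0 ± 17822 counts and VIM down from 40749 ± 2653 to 3844 ± 72.4.

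In the hypoxia and glycolysis list 12 of 16 genes rose and 3 fell (camera adjusted p = 0.0699, or 0.0487 without FT671_NEUR replicate 3), with the glucose transporter gene SLC2A3 up from 4583 ± 202 to 79474 ± 3146 counts. Notch genes were lower in 7 of 10 cases and higher in 2 (adjusted p = 0.186), with the Notch effector HEY1 down from 350.9 ± 34.7 to 19.8 ± 4.92 and the ligand JAG1 from 4345 ± 266 to 993.4 ± 53.8. Rises and falls were 10 and 2 of 16 for cholesterol synthesis (adjusted p = 0.233, with 9 and 4 by TMM and 8 and 4 by library totals), 3 and 6 of 10 for WNT targets (adjusted p = 0.509), 6 and 5 of 12 for TGF-beta and BMP targets (adjusted p = 0.824), 6 and 7 of 19 for integrated stress (adjusted p = 0.969), 5 and 6 of 12 for neural crest (adjusted p = 0.824) and 3 and 4 of 8 for mesoderm (adjusted p = 0.824). They were 1 and 1 of 4 for endoderm (adjusted p = 0.922), 3 and 1 of 6 for glia (adjusted p = 0.734), 2 and 3 of 6 for midbrain, hindbrain and spinal cord (adjusted p = 0.747), 2 and 2 of 4 for ventral and hedgehog genes (adjusted p = 0.922) and 3 and 0 of 3 for germline genes (adjusted p = 0.186). In the lists of this and the preceding 2 paragraphs the counts were the same adjusted over the list alone, except 5 and 7 for integrated stress. For the WNT and integrated stress lists the median, mean and test differed in sign.

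Between FT671 and vehicle limma called 10627 of 13310 genes, 5347 higher and 5280 lower, and 2177 and 1916 of these changed at least 2-fold. The split was 5323 higher and 5315 lower with size factors recomputed from the table. More genes were lower than higher by TMM (5067 higher and 5534 lower), by library totals alone (4583 and 5893) and among genes with a mean of at least 100 counts (4354 and 4560).

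**Figure D2:**
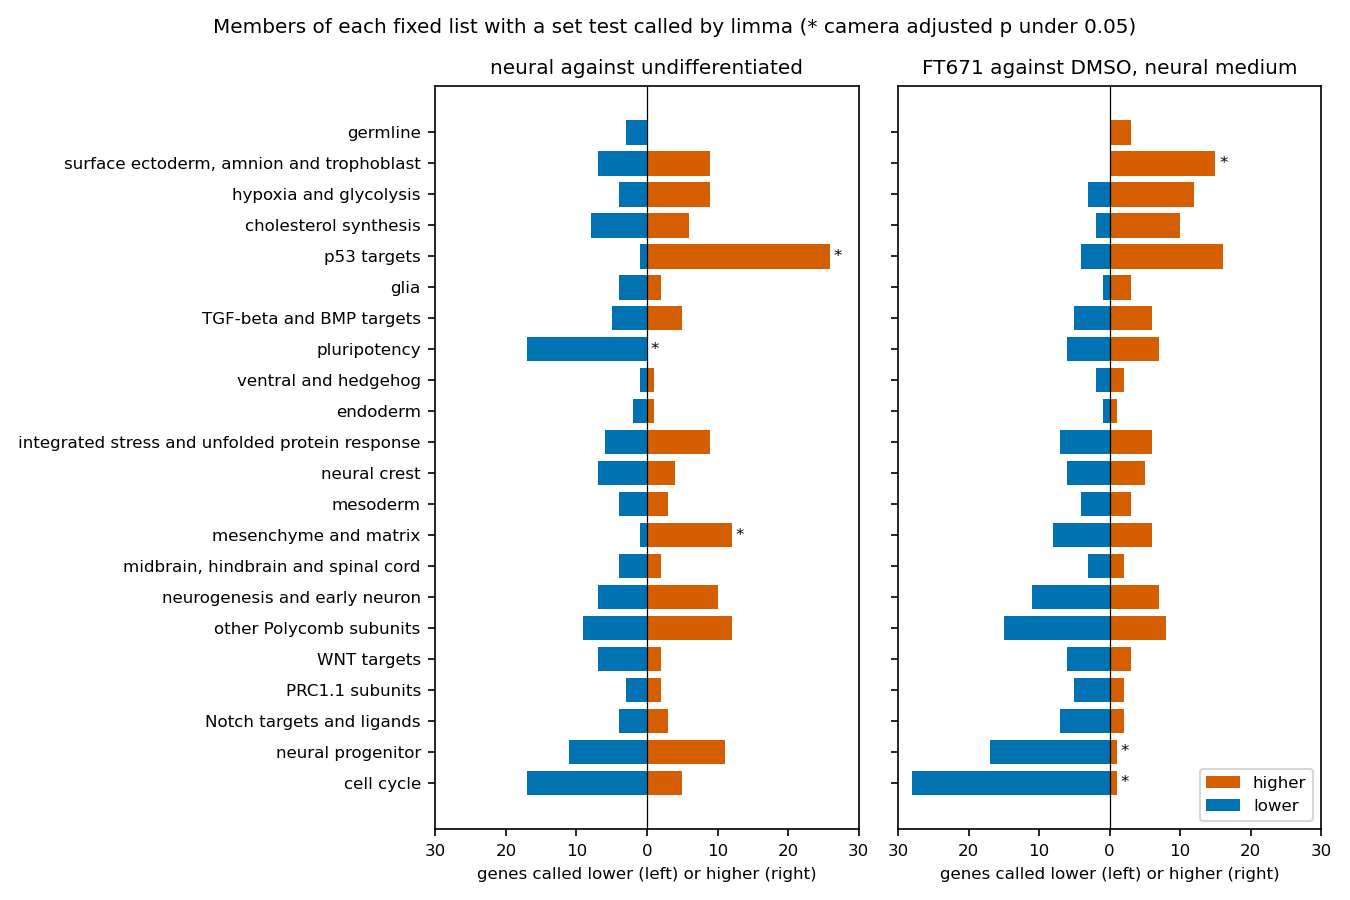
Number of genes called higher (to the right) and lower (to the left) in each fixed list with a list test, for neural against undifferentiated cells and for FT671 against vehicle, with an asterisk where limma camera with the preset correlation passed. The neural progenitor list had 11 higher and 11 lower genes in differentiation, and 1 higher and 17 lower with FT671.

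Vehicle against untreated neural cells shows what the solvent alone went with. A small set of epithelial genes was lower with DMSO. KRT7 had 508.9 ± 71.1 counts against 1023 ± 151 in untreated cells (log2 fold change −1.01 ± 0.11, adjusted p = 3.89e-04), CDH1 918.1 ± 90.1 against 1423 ± 144 (−0.63 ± 0.08, adjusted p = 0.00112), and HES2, a transcription factor of the HES family, 42.8 ± 1.69 against 95.4 ± 13.6 (−1.13 ± 0.13, adjusted p = 4.06e-04). The glucose transporter gene SLC2A3 was also lower (−0.55 ± 0.07, adjusted p = 6.99e-04), as was ZFP42 (−0.60 ± 0.09, adjusted p = 0.00799). SCEL had 13.9 ± 3.96 against 34.8 ± 2.31 counts (adjusted p = 0.0140, or 0.0538 without DMSO_NEUR replicate 1), and EPCAM, an epithelial adhesion gene, 860.3 ± 27.5 against 1219 ± 141 (adjusted p = 0.0117, or 0.0616 without DMSO_NEUR replicate 2).

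Of the 16 genes for surface ectoderm, amnion and trophoblast 3 fell with vehicle, or 9 adjusted over the list alone, and 0 rose (camera adjusted p = 6.98e-13, and adjusted p = 0.0369 with an estimated correlation). Other Polycomb subunits were higher as a list by camera (adjusted p = 0.0371, and adjusted p = 0.212 with an estimated correlation), with 0 of 25 members called by limma over all genes or over the list alone. That list call ended without NEUR replicate 1 (adjusted p = 0.171) or 2 (0.127), and without DMSO_NEUR replicate 1 (0.0652) or 2 (0.116). Targets of p53 had an adjusted p of 0.0518, with 0.0215 without NEUR replicate 3 and 0.0354 without DMSO_NEUR replicate 1. Mesenchyme and matrix genes (adjusted p = 0.131) passed without NEUR replicate 3 (0.0218) or DMSO_NEUR replicate 3 (0.0282), and cholesterol synthesis genes (adjusted p = 0.140) without DMSO_NEUR replicate 3 (0.0105). The remaining 17 tested lists had adjusted p-values from 0.203 to 0.860. Over all genes, 2 pluripotency genes fell, and 1 gene fell in each of the mesoderm and hypoxia lists. Adjusted over the list alone, 1 pluripotency gene rose and 2 fell, 1 gene rose for matrix, 1 rose and 2 fell for TGF-beta and BMP targets, 2 fell for WNT targets, and 1 fell in each of the neural progenitor, mesoderm, ventral and hypoxia lists. For 5 lists, none of them called, the median, mean and test differed in sign.

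In all, 53 of 13310 genes differed between vehicle and untreated neural cells by limma, with 1 higher and 52 lower. The higher gene was CACNA1F, a calcium channel gene named after its values were seen (1.65 ± 2.08 to 10.0 ± 4.75 counts, adjusted p = 0.0354). By edgeR, at pseudocounts of 0.1 and 10, and without NEUR replicate 2 or DMSO_NEUR replicate 1 or 3, 0 genes were higher. With 1 of the other libraries left out 1 gene was higher, and by DESeq2 7 were. The count of all genes called fell to 24 without DMSO_NEUR replicate 1, to 30 without replicate 2 and to 31 without replicate 3. It was 0 when only these 2 groups were fitted by limma, and 111 by DESeq2 and 66 by edgeR. In the fit of 2 groups 729 of 13310 genes had an unadjusted p under 0.05 by limma. That is close to the number such a cutoff passes where nothing differs.

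Vehicle libraries against undifferentiated cells show the differentiation in DMSO. POU5F1 fell from 2459 ± 172 to 1.62 ± 1.48 counts (log2 fold change −10.09 ± 0.48, adjusted p = 5.60e-12) and PAX6 rose from 176.4 ± 20.8 to 3985 ± 250 (4.50 ± 0.16, adjusted p = 9.83e-14), both named here after their values were seen. With vehicle 10660 genes were called against undifferentiated cells, 5208 higher and 5452 lower, with 2015 and 2225 changed at least 2-fold. By library totals alone 4332 were higher and 6296 lower, and among genes with a mean of at least 100 counts 4700 were higher and 4097 lower.

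FT671 libraries against undifferentiated cells show how far treated cells were from the starting state. POU5F1 was lower by −8.96 ± 0.48 on the log2 scale (adjusted p = 1.21e-11) and SOX2, a transcription factor of pluripotent and neural progenitor cells, by −9.40 ± 0.16 (adjusted p = 7.05e-18), from 9263 ± 1307 to 13.0 ± 3.96 counts. KRT7 was higher (5.78 ± 0.11, adjusted p = 2.00e-17), as was COL17A1 (7.08 ± 0.16, adjusted p = 2.66e-16). These genes were chosen for this comparison after their values were seen. With FT671 11711 genes were called, 5863 higher and 5848 lower, and 3170 and 3057 of these changed at least 2-fold. The split was 5836 and 5876 with recomputed size factors, 5696 and 6009 by TMM, 4789 and 6750 by library totals alone, and 5090 and 4634 among genes with a mean of at least 100 counts.

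Whether FT671 moved differentiation genes back was asked across the 10917 genes called between neural and undifferentiated cells. In 46.4% of them (5067) the fold change with FT671, whether or not it passed the test, had the opposite sign to that in differentiation. The log2 fold changes correlated with Pearson r −0.162 and Spearman rho −0.0282 across genes, which are not independent replicates. Of the 5376 genes that rose in differentiation, 1803 fell with FT671 (2133 if independent, odds ratio 0.647, Fisher's exact p = 6.75e-33) and 2295 rose further (2160 if independent, odds ratio 1.19, p = 1.14e-06 by Fisher's exact test). Of the 5541 that fell, 1972 rose with FT671 (2226 if independent, odds ratio 0.719, Fisher's exact p = 7.78e-20) and 2191 fell further (2198 if independent, odds ratio 0.991, Fisher's exact p = 0.801). The Fisher tests also count genes as independent, and both sets of calls rest on 1 variance per gene. Their p-values and the counts under independence are therefore descriptive only. Among genes changed at least 2-fold in differentiation, 52.8% had opposite signs, and over all genes tested 46.7% had.

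**Figure D3:**
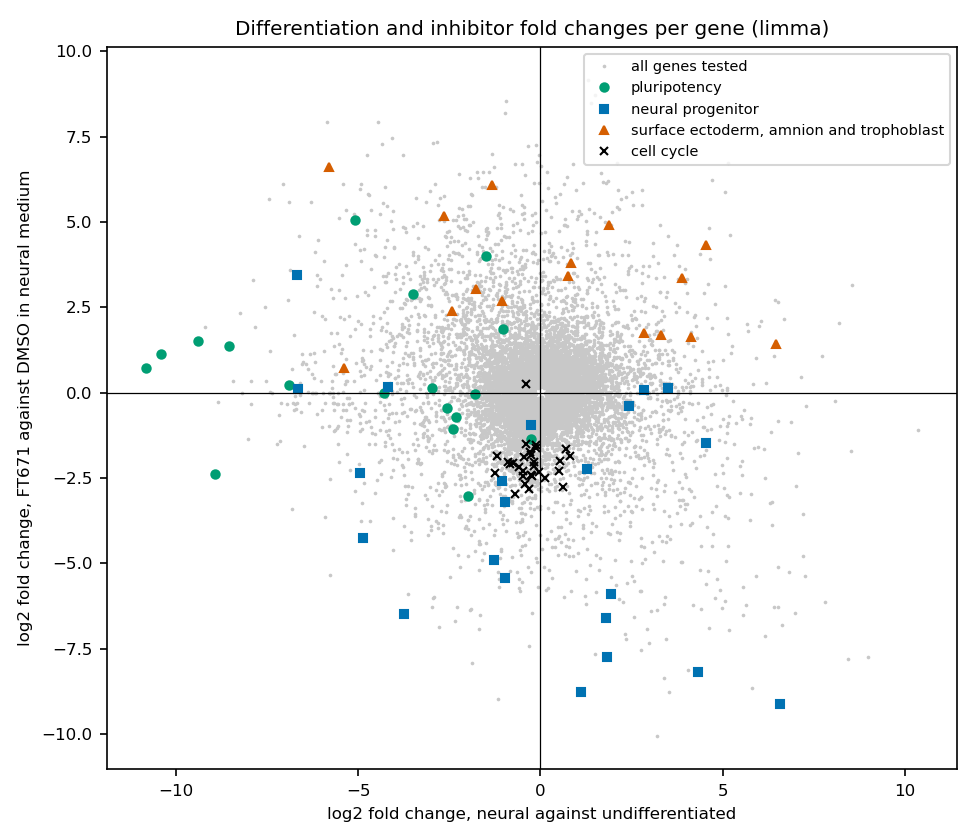
Log2 fold change of each gene in FT671 against vehicle (vertical) and in neural against undifferentiated cells (horizontal), with members of 4 fixed lists in colour and all other genes in grey. Across the 10917 genes called in differentiation, 46.4% lie on opposite sides of 0 on the axes.

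The differentiation score was −4.72 ± 0.10 in undifferentiated, 4.17 ± 0.02 in neural, 4.18 ± 0.10 in vehicle and 2.33 ± 0.04 in FT671 libraries (SD, n = 3). The difference of −1.85 between FT671 and vehicle was larger than the spread between replicates. It was −3.07 with 50 and −1.42 with 500 genes per direction. Its exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow. The 200 genes with the largest rise averaged 5.29 log2 CPM with vehicle, 4.45 with FT671 and 0.55 in undifferentiated cells. The 200 with the largest fall averaged 1.11, 2.12 and 5.27 in the same order. Genes chosen for the largest changes can lose part of them in any strong change. The score therefore does not decide whether FT671 moved cells back. Across all genes FT671 libraries correlated less with undifferentiated ones (Pearson r 0.656 to 0.664) than vehicle libraries did (0.781 to 0.791).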

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

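Of the tests in this part, those of carried-over cells or RNA and of a single untreated library were chosen only after the result was seen, and the epithelial junction list was written after it too.

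The effect of differentiation differed between cultures with DMSO and untreated cultures at 53 genes, tested directly as vehicle against untreated neural cells in limma. Of these genes 52 were lower with vehicle. They included the epithelial genes KRT7 and CDH1. The count was 24 without DMSO_NEUR replicate 1, 30 without replicate 2 and 31 without replicate 3, and 0 with only the 2 groups compared in the fit. Of the 52, 47 were higher with FT671 than in untreated cells and 4 were lower, against 39.2% higher among all genes. Splits of the 6 libraries were too few for a share under 0.05, with 53 genes for the real split and 2 for the highest other.

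Cells or RNA like those of the FT671 cultures in the untreated libraries would have brought their abundant transcripts along. The share was the excess of untreated over vehicle libraries, in percent of the excess of FT671 over vehicle libraries. Its median was 0.176% (−0.0257% to 1.35%) over 7 genes abundant with FT671 and far lower with vehicle. Among them were COL17A1 (13386 and 128.1 counts) and VGLL1 (1367 and 13.0). The median was 4.05% for the 47 genes, but these were called for their excess in untreated libraries, which raises their share. The gap between the medians therefore does not decide against that source. The low shares of the 7 genes leave a small amount of it open. SCEL, also among the 53 genes, had 34.8 counts in untreated and 13.9 in vehicle libraries, while CASP4 had 2.64 and 2.93. The number of genes was 56 without NEUR replicate 3, which argues against a single deviating untreated library. A smaller share of epithelial-type cells in the vehicle cultures may also remain as an explanation. Of 34 epithelial junction genes outside the 53, 29 (85.3%) were lower with vehicle, against 49.5% of all other genes. Lower expression within cells would give the same, so these values do not favour a smaller share. An effect of DMSO on the cells and a difference between culture batches stay open, since the libraries carry no measure that separates them.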

How the results depend on the processing

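Settings tested only after the data were seen were the edgeR test, TMM scaling, a mean of at least 100, a pseudocount of 2 and, for the 8 lists written later, each library left out. Under every alternative run the counts of genes called stayed within 1.5 times of the reported value for neural against undifferentiated (9031 to 11021), FT671 against vehicle (8914 to 11019), vehicle against undifferentiated (8797 to 10862) and FT671 against undifferentiated (9724 to 11934). The balance of higher and lower genes did not hold in every setting. In FT671 against vehicle, more genes were higher in the reported fit (5347 and 5280) and fewer by edgeR (5090 and 5538), TMM (5067 and 5534), library totals (4583 and 5893) and a mean of at least 100 (4354 and 4560). In neural and in vehicle against undifferentiated cells more genes were higher with that filter alone. In FT671 against undifferentiated cells the near-even split tipped either way. Filters at 1 CPM or a mean of 10 removed no gene and gave no value. Library totals alone as the scale shifted the median of all genes to −0.17, −0.11, −0.18 and −0.27 (log2) in those comparisons.

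For vehicle against untreated (53) the count was 111 by DESeq2 and 14 at an adjusted p under 0.01, which is stricter by construction. It was 24 (without DMSO_NEUR replicate 1) to 56 with 1 library left out (30 without DMSO_NEUR replicate 2, 31 without replicate 3). With only the 2 groups fitted it was 0. In that fit 729 of 13310 genes had an unadjusted p under 0.05 in limma, close to the number passed where nothing differs. Such a fit rests on fewer samples, but it called more genes than reported in FT671 against vehicle (11019) and vehicle against undifferentiated (10862). It called fewer in neural against undifferentiated (10434), and the cause of the 0 was not tested. Lists passing were 3, 3 and 2 in neural against undifferentiated, FT671 against vehicle and vehicle against untreated. With an estimated correlation they were 2, 0 and 1. By fry, which does not compare a list with other genes, they were 19, 19 and 2. With 1 library left out, vehicle against untreated gave 1 (without NEUR replicate 1 or 2, or DMSO_NEUR replicate 2) to 4 lists (without NEUR replicate 3 or DMSO_NEUR replicate 3). Genes opposite to differentiation were 52.8% among those changed at least 2-fold. Pearson r was −0.148 over all genes and −0.210 over those, and Spearman rho −0.00938 and −0.170. The score difference was −3.07 with 50 and −1.42 with 500 genes per direction. Where no reason is given, the cause was not tested.

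Of 105 named genes in FT671 against vehicle, the call of 1 (GFAP) ended by DESeq2, and of 2 (GFAP, STAG3) with 1 library left out. Of 11 in vehicle against untreated, 6 calls ended with 1 library left out. Of the 8 lists written later, the ribosomal protein list was lower in vehicle than untreated cells (camera adjusted p = 6.75e-04, and adjusted p = 0.610 with an estimated correlation). It was not called and pointed the other way without NEUR replicate 3 (0.483), and had 2.58e-06 to 0.0261 with 1 other library left out. No other call of the 8 lists changed with 1 library left out. Depth limits genes with few reads, whose folds against 0 reads are bounds only.

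Replicate numbers did not pair the libraries. Pairing was read from each library's deviation from its group mean, across genes with a mean of at least 100 counts. In no comparison did every deviation correlate best with that of its own number. The r between deviations of the same number ran from −0.303 to 0.115. The block ended the calls of GFAP in FT671 against vehicle (adjusted p = 0.0521) and of LCK (0.0597) and KRT18 (0.0601) in vehicle against untreated. With replicate block the counts were 10817, 10527, 41, 10553 and 11648 genes in the order of the comparisons in the report, with 3, 3 and 2 lists.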

Other observations

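The tests of scale, of a mislabelled group, of lost cells and of undifferentiated cells as the whole cause, and those of the squamous and trophoblast lists, were chosen only after the results were seen, as were the genes and the 8 lists named in this part.

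Beyond the fixed lists, FT671 cultures carried genes of stratified and squamous epithelium. LAMB3, a chain of the basement membrane laminin of epidermis, rose from 181.6 ± 19.1 counts with vehicle to 9641 ± 553 (log2 fold change 5.73 ± 0.11, adjusted p = 9.67e-17, n = 3 per group in limma), the hemidesmosome integrin ITGB4 from 153.7 ± 13.9 to 9478 ± 323, and the keratin KRT17 from 2.27 ± 0.572 to 1365 ± 86.0. Of 24 squamous genes 22 rose and 2 fell, and of 34 epithelial junction genes 33 rose and 1 fell (camera adjusted p = 4.51e-12, and adjusted p = 0.00649 with an estimated correlation). Lysosomal genes rose in 21 of 22 cases and fell in 1 (adjusted p = 7.03e-06, and adjusted p = 0.0209 with an estimated correlation), with the membrane protein gene LAMP2 from 2306 ± 7.73 to 5805 ± 89.7. Class I antigen presentation genes rose in 12 of 15 cases and fell in 2 (adjusted p = 0.00857, and adjusted p = 0.222 with an estimated correlation), with B2M from 2150.0 ± 251 to 4831 ± 337. Interferon response genes rose in 11 of 17 cases and fell in 4 (adjusted p = 0.0985), imprinted genes in 6 and 7 of 17 (adjusted p = 0.913), and ribosomal protein genes in 3 and 4 of 25 (adjusted p = 0.913, with 2 and 8 by library totals). The imprinted growth genes IGF2 (454.6 ± 130 to 11141 ± 382) and H19 (6693 ± 1931 to 56105 ± 2746) both rose, and SOX2 fell from 1585 ± 134 to 13.0 ± 3.96.

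In neural against undifferentiated cells, 24 of 25 ribosomal protein genes fell (camera adjusted p = 4.09e-04, and adjusted p = 0.536 with an estimated correlation). Lysosomal genes rose in 17 of 22 cases and fell in 2 (adjusted p = 0.00129, and adjusted p = 0.196 with an estimated correlation), or 15 and 4 by library totals, and interferon response genes rose in 13 of 17 and fell in 2 (adjusted p = 0.0170, and adjusted p = 0.196 with an estimated correlation). Rises and falls were 12 and 17 of 34 for epithelial junctions (adjusted p = 0.493), 16 and 6 of 24 for squamous epithelium (0.0743), 5 and 6 of 13 for trophoblast (0.650, with 6 and 6 by TMM), 9 and 2 of 15 for class I (0.0996) and 9 and 5 of 17 for imprinted genes (0.634). With vehicle against untreated cells, lists were lower for epithelial junctions (adjusted p = 3.18e-09, and adjusted p = 0.0164 with an estimated correlation), squamous epithelium (2.58e-10, and adjusted p = 6.31e-04 with an estimated correlation), interferon response (7.67e-04, and adjusted p = 0.0744 with an estimated correlation) and ribosomal proteins (6.75e-04, and adjusted p = 0.610 with an estimated correlation). Members called lower were 0 of 34, 5 of 24, 1 of 17 and 0 of 25 in that order, and none was called higher. The ribosomal list was no longer called, and pointed the other way, without NEUR replicate 3 (adjusted p = 0.483). The other 4 of these lists had adjusted p-values from 0.293 to 0.775.

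In FT671 cultures most neural progenitor genes fell and epithelial ones rose, with list medians of −2.89 and 3.20 (log2). Neither list passed camera with an estimated correlation (adjusted p = 0.371 and 0.194). Genes of neurogenesis moved both ways (7 higher and 11 lower). The 10 most abundant genes, FN1 among them, can shift the scale between vehicle and FT671 by 0.0541, which argues against that as the cause. The pluripotency list had a median of −3.15 against undifferentiated cells, which argues against undifferentiated cells under a wrong label. Loss of neural cells with outgrowth of others and a change within cells cannot be told apart in bulk RNA: the 17 neural progenitor genes that fell kept a median of 1.27% of the vehicle level (0% to 76.0%). Splits of the 6 libraries were too few for a share under 0.05, with 10627 genes for the real split and 0 for the highest other. Mixed splits put the group difference into the spread, so the 0 does not bear on chance.

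Both the squamous and the trophoblast list were written after the epithelial rise was seen, so their tests do not decide whether either program describes it. The squamous list, without members of the fixed lists, was higher with FT671 (camera adjusted p = 2.05e-09, and adjusted p = 9.996e-04 with an estimated correlation). In the trophoblast list 9 of 13 genes were higher and 3 lower (adjusted p = 0.0985, and adjusted p = 0.190 with an estimated correlation). HLA-G rose from 83.0 ± 8.97 to 1768 ± 99.3 counts and SIGLEC6 from 8.42 ± 3.89 to 775.7 ± 46.6, while TFPI2 fell from 11708 ± 1642 to 997.8 ± 52.7. Both lists hold genes that other epithelia express, so neither names a cell type.

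NEUR replicate 3 stood apart from the other untreated neural libraries, with a chi-square per gene of up to 26.0 between these libraries. Across 10913 genes its deviation followed transcript length (Spearman rho −0.643, against 0.193 for replicate 1 against 2) and GC content (0.426, against −0.298), and genes are not independent replicates. A technical difference in RNA or library preparation is a candidate explanation. Among genes with a mean of at least 1000 counts, 2322 were lower in it than in both other libraries, by a median of 14.2% (9.67% and 6.92% for replicates 1 and 2 taken the same way). Part of such a fall comes from choosing the lower genes, so it sets no exact share of other cells. Of the 2322 genes 36.0% were not lower in undifferentiated cells (30.5% and 34.5% for replicates 1 and 2), which such cells would not lower. For 16 genes far lower in the other neural libraries than in undifferentiated cells, the median excess was 0.109% of their undifferentiated level (−0.150% to 0.708%). The small marker excess, set against a fall larger than in replicates 1 and 2, argues against undifferentiated cells as the whole cause and leaves a trace of them open. The 36.0% adds little, since replicates 1 and 2 gave 30.5% and 34.5%.

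The 10 splits were too few for a share under 0.05 for neural against undifferentiated as well (10917 genes, and 0 for the highest other), for vehicle against undifferentiated (10660, and 0) and for FT671 against undifferentiated (11711, and 0). In each comparison 1 of the 10 splits, the real one, gave as many genes. A split that mixes groups puts any difference between them into its spread, so its low count does not bear on chance.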
